A study of Homo sapiens with 3 samples.

How the data were processed

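RNA of THP-1 cells was measured on 3 Affymetrix whole-transcript arrays, 1 each for untransfected cells (WT), the scrambled-vector clone SCR4 and the DAP12 knockdown clone SI17. The deposited table gives log2 expression values for 33297 probe sets. RMA and Affymetrix Expression Console are named in the submitters' processing notes, and their versions, the probe set level, the genome build and the annotation were not given in the sources used here. That the deposited values are on a log2 scale was taken from their range, 1.06 to 14.36, and from RMA's usual output. Further clones that the design text names were not analysed here.

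Probe sets were named through the platform annotation supplied with the table. Of these, 19460 had 1 gene symbol, 1754 had several and 12083 were not listed with a gene, and names were taken only from the first kind. Gene IDs of 19429 named probe sets matched the GRCh38.p14 gene table, which was used for chromosome names and gene order only. A gene was represented by its probe set with the highest mean over the 3 arrays, giving 18417 genes, of which 769 had more than 1 probe set. Genes were kept where the highest of the 3 arrays reached 7.61, the median of all values of named probe sets, which left 9475. No detection calls were used, so a gene under that value on an array may be at background there, and a fold against it may understate the true difference.

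With 1 array per group no test between groups was run. Differences of log2 values were taken for SI17 minus SCR4, SI17 minus WT and SCR4 minus WT, and a gene was said to stand apart in an array when it differed by at least 2-fold in the same direction from both others. SI17, SCR4 and WT (given as both clones against WT) were treated alike. Counts in SI17 and the correlation of its 2 comparisons, which share the SI17 array, were set beside 1000 simulated sets without a knockdown effect, with spread drawn from SCR4 minus WT for genes of like expression. Since that spread holds the departures of the SCR4 clone, the simulation stands for clone-to-clone differences of that size and not for technical noise alone. Each gene was drawn on its own, so the simulated ranges leave out that genes move together.

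Before the data were examined, 36 gene lists were fixed, covering DAP12 partners, myeloid functions, other cell types, stress, metabolism and basic cell functions. Each list with at least 5 expressed genes was described by its median difference and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. The lowest and the highest 2.5 percent were called the tails, which would take in 5 percent of unrelated lists. Chromosomes were treated the same way, without Y-linked genes. The named genes were also fixed beforehand. They are TYROBP, the 12 highest and 12 lowest genes apart in SI17 by the smaller of both differences, the 6 highest and 6 lowest apart in SCR4 and in both clones against WT, up to 4 members of each list described with the largest such difference (or, for a single pair of arrays, the largest difference), and all expressed DAP12 partners. Small RNA genes, pseudogenes, Y-linked genes and provisional symbols were counted but not named.

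Alternatives fixed beforehand were filters at the 25th and 75th percentiles or none, arrays centred on the median of filtered genes, cyclic loess, quantile normalization, the mean of a gene's probe sets, thresholds of 1.5-fold and 3-fold and list means. Alternatives chosen after seeing the data left out genes in shifted chromosome runs, left out genes with exactly equal values, or used chromosome means. The runs themselves, the equal values and the position of WT between the clones were also examined only after the data had been seen.

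The counting step was tested on simulated data of 9475 genes. It recovered 1 of 50 genes changed by a log2 difference of 0.58, 49 of 50 at 1.5, 50 of 50 at 2 and 50 of 50 at 3, and it also called 43 unchanged genes. The list step placed 10 of 200 unshifted lists outside the tails. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for the normalizations.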

Results

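Gene expression was measured on 3 whole-transcript arrays of THP-1, a human line from an acute monocytic leukaemia whose cells resemble monocytes. The first array held untransfected cells (WT). The second held SCR4, a clone carrying a vector with a scrambled sequence, and the third held SI17, a clone carrying a hairpin vector directed at DAP12, the adaptor protein encoded by TYROBP. Each group had 1 array, so no difference had a replicate check, no p-value was computed, and the number of arrays limits the precision. The array medians were 7.03 in WT, 7.02 in SCR4 and 6.99 in SI17 (log2). Of 18417 genes with their own symbol, 9475 passed the expression filter, and over these the correlation across genes was 0.987 between SI17 and WT, 0.978 between SCR4 and WT and 0.960 between SI17 and SCR4. Genes are not independent replicates, and these correlations describe the arrays only.

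The targeted gene, TYROBP, had a log2 level of 12.20 in WT, 12.56 in SCR4 and 10.75 in SI17. It was 3.50-fold lower in SI17 than in SCR4 and 2.73-fold lower than in WT, and SCR4 stood above WT by 0.36. Among 11 expressed genes fixed as receptors and adaptors linked to DAP12, TYROBP was the single member at least 2-fold lower in SI17 than in both other arrays. TREM2, a receptor that signals through DAP12, was close to the filter value on every array, at 7.71 in WT, 7.71 in SCR4 and 7.70 in SI17. CSF1R, the receptor for macrophage colony-stimulating factor, differed by -0.96 between SI17 and SCR4 and by -0.28 between SI17 and WT. HCST (DAP10), the related adaptor, differed by -0.67 from SCR4 and by 0.14 from WT. FCER1G, another adaptor with an immunoreceptor activation motif, differed by -0.25 from SCR4 and by 0.07 from WT. The median of the 11 genes, TYROBP included, was -0.25 for SI17 minus SCR4, at percentile 0.21 of 10000 random lists matched on expression. It was 0 for SI17 minus WT, at percentile 39.6, and 0.31 for SCR4 minus WT, at percentile 100. The list median was therefore low against SCR4, which stood above WT, and not against WT.

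The central question was which genes differed in the knockdown clone from both the scrambled clone and the untransfected cells. Besides TYROBP, the lowest genes in SI17 included ALX1, a homeobox transcription factor of craniofacial development, at 4.72 against 11.16 in WT and 11.02 in SCR4. This was 78.7-fold below the nearer array. CD4, the coreceptor carried by helper T cells and monocytes, was 5.65-fold below the nearer array, at 8.62 in SI17, 11.12 in WT and 11.44 in SCR4. NAV3, a microtubule-binding protein, was 5.12-fold lower, and SERPINF1, which encodes the secreted antiangiogenic factor PEDF, was 5.01-fold lower. TCF4, a basic helix-loop-helix factor of plasmacytoid dendritic cells, was 3.42-fold lower, ZNF426, a zinc finger gene, 3.23-fold, and SLC8A1, a sodium-calcium exchanger, 2.89-fold. The receptor phosphatase PTPRO was 2.64-fold lower, PARP15 2.59-fold, the class II gene HLA-DPA1 2.47-fold and PPARGC1A, a coactivator of mitochondrial biogenesis, 2.46-fold. PTPRO was under the expression filter value in WT and SI17, at 7.58 and 6.18, so its difference from WT may lie at background. ALX1, NAV3, TCF4, ZNF426, SLC8A1, PARP15, HLA-DPA1 and PPARGC1A were under that value in SI17 alone, where they may be at background. CD4, SERPINF1 and TYROBP were over it on every array.

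In the other direction, PPP2R3A, a regulatory subunit of protein phosphatase 2A, was 3.84-fold higher in SI17 than in the nearer array. It was at 8.42 in SI17, 6.48 in WT and 5.65 in SCR4. C3AR1, the receptor for complement fragment C3a, was 3.02-fold higher, at 10.70 in SI17, 9.11 in WT and 8.01 in SCR4. POGLUT2, a glucosyltransferase, was 2.67-fold higher, CDK20 2.66-fold, the actin regulator CAP2 2.61-fold, the tetraspanin CD82 2.30-fold and MS4A4A, a macrophage membrane protein, 2.00-fold. PPP2R3A and POGLUT2 were under the expression filter value in both WT and SCR4, and MS4A4A in WT, and may be at background there. Among the 9475 genes over the filter, the 7 higher genes named here stood at least 2-fold above both other arrays and 33 at least 2-fold below both, 40 in all. Under the 25th percentile filter and without a filter there were 8 above and 35 below. Probe sets of several genes added 2 above and 3 below, and those not listed with a gene 4 below. The same rule set SCR4 apart in 87 genes. In 1000 simulated sets without a knockdown effect, with spread drawn from SCR4 minus WT, a mean of 21.6 genes lay above both arrays (95% of sets 13 to 31) and 21.9 below both (13 to 31). The total in SI17 was thus of the size simulated without an effect, while its split lay outside both ranges. The simulation drew each gene on its own, whereas real genes move in groups, so its ranges may be too narrow to judge that split. Its spread was also wider than that of SI17 minus WT, with standard deviations of 0.275 for SCR4 minus WT and 0.210 for SI17 minus WT. The lower count was near the upper limit, and with quantile normalization there were 7 above and 31 below, inside the simulated range below. Without genes in shifted chromosome runs 24 of the 40 genes were left, 5 above and 19 below, though the simulation was not repeated without them. That setting was chosen after seeing the data, and the runs were found from the same differences. Of the 40 genes, 1 above and 9 below lay in SI17 minus WT runs of their own direction. The rest of those left out lay in other runs.

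**Figure D1:**
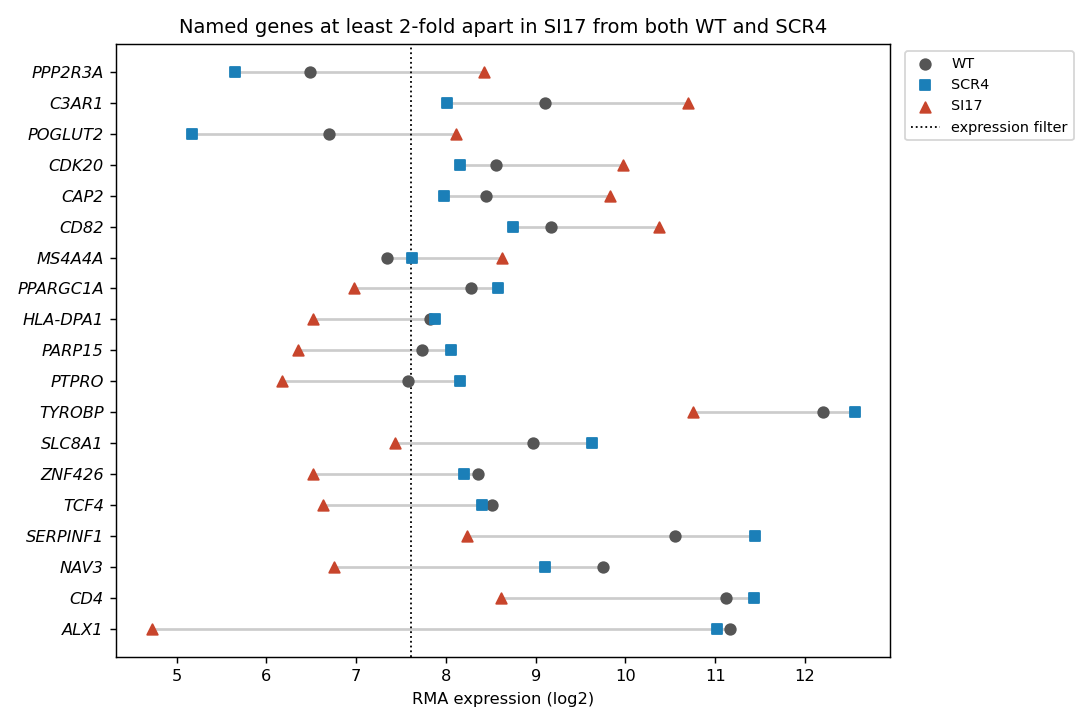
Log2 expression of the named genes that stood at least 2-fold apart in SI17, with 1 point per array (WT, SCR4, SI17) and a dotted line at the expression filter of 7.61. ALX1 shows the widest gap among these genes, from 11.16 in WT to 4.72 in SI17, and TYROBP lies at 12.20, 12.56 and 10.75 in WT, SCR4 and SI17.

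Of 33 fixed gene lists with at least 5 measured genes, 8 had medians below the 2.5th percentile of random lists both for SI17 minus SCR4 and for SI17 minus WT. This number depended on the filter, with 6 lists under the 25th percentile filter, 5 under the 75th and 5 without a filter. It was 7 without genes of equal values, an alternative chosen after seeing the data. Some lists share members, so the 8 are not separate results. Random medians for SI17 minus WT spread little, with standard deviations of 0.018 for integrins and 0.011 for interferon-stimulated genes. Medians close to 0 could therefore fall below the 2.5th percentile. For SI17 minus WT alone, 4 lists were above and 9 below the tails, and without a filter 6 and 5. HLA class II and antigen presentation genes, with 6 measured of 17 listed, had medians of -0.80 against SCR4 and -0.42 against WT. Of these members, 6 of 6 and 5 of 6 were lower. HLA-DPA1 differed from WT by -1.30, HLA-DPB1 by -0.83, HLA-DRB5 by -0.72 and HLA-DMA by -0.12. HLA-DPA1, HLA-DPB1 and HLA-DRB5 were close to the expression filter value in WT, at 7.82, 7.89 and 7.79. In SI17 they were under it, at 6.52, 7.07 and 7.07, and may be at background there. HLA-DPA1 had 3 probe sets, and its value moved under an alternative processing. Monocyte and macrophage markers had medians of -0.43 and -0.11 over 20 genes, of which 13 were lower than in SCR4 and 14 lower than in WT. Among them CD4 differed from WT by -2.50, the macrophage glycoprotein CD68 by -1.12, the integrin ITGAX (CD11c) by -0.89 and the chemokine receptor CCR2 by -0.54. Interferon-stimulated genes had medians of -0.35 and -0.04 over 22 genes, and the antiviral genes TRIM22, IFI16 and OAS2 differed from WT by -1.08, -1.02 and -0.63, with IFI6 at -0.47. OAS2 was under the filter value in both WT and SI17, at 7.27 and 6.64, so its difference from WT may lie at background. Lysosome and protease genes had medians of -0.20 and -0.05 over 24 genes, with CTSL at -1.08, GAA at -0.57, MMP2 at -0.56 and LGMN, a protease higher than in both other arrays, at 0.45 against WT.

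Genes of signalling through immunoreceptor activation motifs had medians of -0.10 and -0.03 over 26 genes. The Src-family kinase FYN differed from WT by -0.79, the adaptor BLNK by -0.33, SOS1 by -0.22 and the phospholipase PLCG1 by 0.14. For chemokine and chemoattractant receptors the medians were -0.75 and -0.37 over 7 genes. CX3CR1 (-0.59 against WT), CCR2 (-0.54) and CCR1 (-0.44) were lower, whereas C3AR1 (1.59) was higher. Complement and Fc receptor genes (-0.29 and -0.12 over 12 genes) held C2, lower than WT by a difference of -1.74, CFP at -0.39, ITGAX and again C3AR1. For integrins and adhesion genes the medians were -0.12 and -0.02 over 19 genes, with CD82 (1.20), CD44 (0.72), ITGAX (-0.89) and SELPLG (-0.45) against WT. Heat shock genes and mitochondrial respiratory chain genes were the 2 lists above the matching upper tail in both comparisons. Heat shock medians were 0.29 against SCR4 and 0.16 against WT over 11 genes, with HSPE1 at 0.33, HSPH1 at 0.31, HSPA4 at 0.30 and DNAJB1 at 0.22 against WT. Respiratory chain medians were 0.12 and 0.08 over 36 genes, with NDUFS3 at 0.30, NDUFA5 at 0.28, NDUFS4 at 0.26 and ATP5F1A at 0.21. By list means in place of medians, 5 of the 8 lower lists and both higher lists were again outside the tails in both comparisons. The other lower lists were not. The means of chemokine receptors and of integrins and adhesion genes were at percentiles 14.2 and 4.08 for SI17 minus WT. That of complement and Fc receptor genes was at percentile 5.07 for SI17 minus SCR4. Random lists ignore that members of a list move together, and selecting lists that differ from both arrays favours lists in which SCR4 itself departs the other way from WT, as it did in 7 of the 8 lower and both higher lists.

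**Figure D2:**
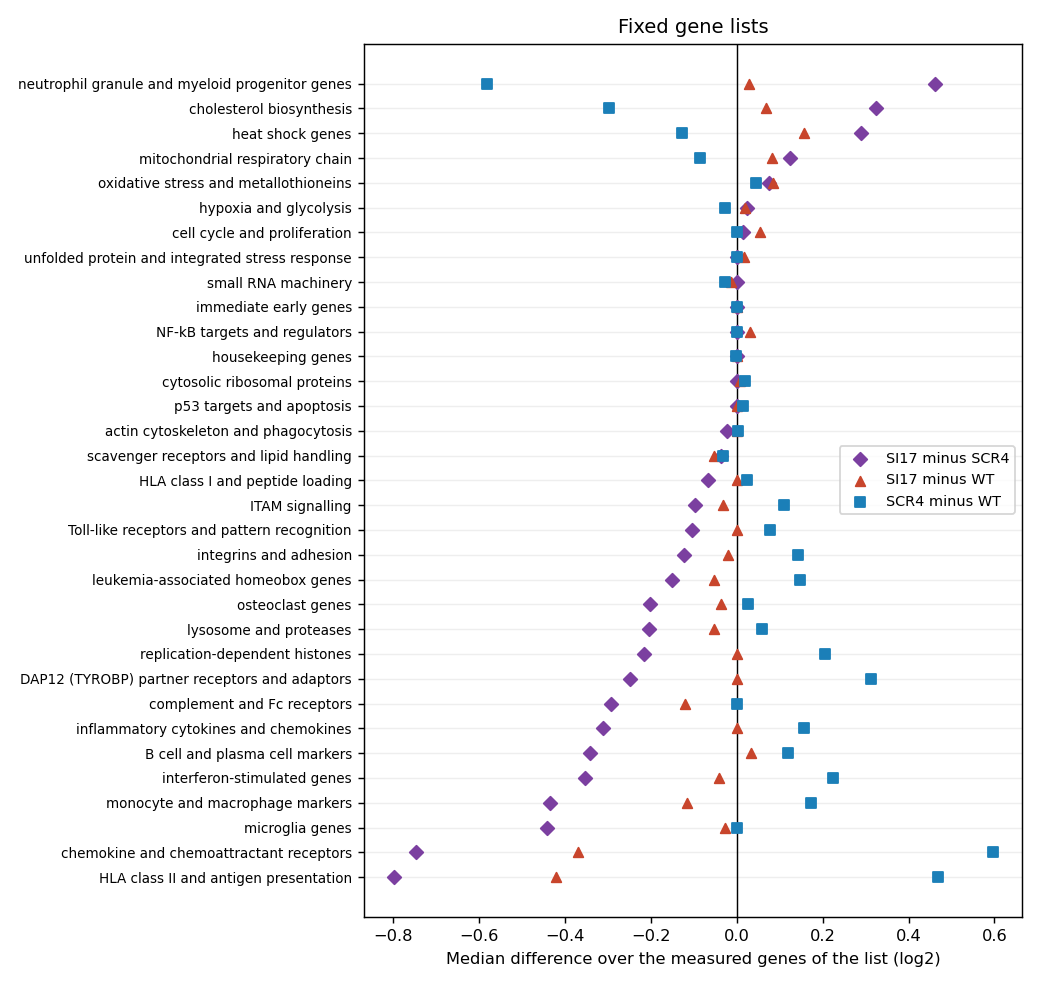
Median log2 difference of the 33 fixed gene lists with at least 5 measured genes, for SI17 minus SCR4, SI17 minus WT and SCR4 minus WT. HLA class II and antigen presentation genes lie at -0.80, -0.42 and 0.47, and neutrophil granule and progenitor genes at 0.46, 0.03 and -0.58.

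Nasu-Hakola disease, named in the study's title, affects bone and brain, and lists of osteoclast and microglia genes had been fixed for that reason. Microglia genes had a median of -0.44 for SI17 minus SCR4 over 9 genes, at percentile 0.06, and of -0.03 for SI17 minus WT, at percentile 6.45. GAS6, a ligand of TAM receptors, differed from WT by -1.80, CX3CR1 by -0.59, OLFML3 by -0.47 and the phagocytic receptor MERTK by -0.39. OLFML3 and MERTK were under the expression filter value in WT, at 7.43 and 7.33, and in SI17, at 6.96 and 6.94. The differences of these genes from WT may therefore lie at background. Osteoclast genes had medians of -0.20 and -0.04 over 10 genes, at percentiles 0.90 and 3.47. CA2, the carbonic anhydrase of acid-secreting cells, differed from WT by -2.25, CSF1R by -0.28, the integrin ITGAV by -0.28 and the chloride transporter CLCN7 by -0.19. CA2 and GAS6 were also lower in SCR4 than in WT, by differences of -1.04 and -0.81. The means of both lists for SI17 minus WT were lower than the medians, at percentiles 0.29 and 0.11, and the osteoclast median against SCR4 was 0.00248 under the 25th percentile filter, which took in 16 genes.

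Markers of other cell types were sparse among the expressed genes. T and NK cell markers had 2 measured genes of 29 listed, erythroid and megakaryocyte genes 3 of 27, and fibroblast and epithelial markers 4 of 22, with medians for SI17 minus WT of -0.08, 0.10 and 0.15. B cell and plasma cell markers had 5 of 22, with a median of 0.03 for SI17 minus WT. Against SCR4 that B cell median was -0.34. Under the 75th percentile filter 1 gene of the list, XBP1, was left, and it differed by 0.39.

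Set directly against the scrambled clone, SI17 had 82 genes at least 2-fold higher and 154 at least 2-fold lower, and against untransfected cells 9 higher and 43 lower. The lower genes against SCR4 included monocyte genes that were high in SCR4, such as the lipid scavenger receptor CD36, at -2.23 against SCR4 and -0.46 against WT. The costimulatory ligand CD86 was at -1.76 and -0.38, and the integrin ITGAL at -1.59 and -0.29. CD86 was under the expression filter value in WT and SI17, at 6.52 and 6.14, so its difference from WT may lie at background. The higher genes included the granule peptide DEFA4, at 3.76 against SCR4 and 0.16 against WT, and the granule enzyme MPO, at 1.98 and 0.54. Both comparisons use the SI17 array, and their differences correlated at 0.686 across genes, against 0.50 (0.463 to 0.535) in simulated sets without a knockdown effect. The same correlation was 0.832 for the comparisons that share the SCR4 array and -0.167 for those that share WT, so a value above 0.50 was not particular to the knockdown clone. The covariance was 0.0537, against 0.0379 simulated, and independent lists of these sizes would share 0.0779 genes higher and 0.699 genes lower in both. Part of the excess over independent lists may come from the shared array, since the simulated sets, which share it, held 21.6 genes higher and 21.9 lower in both. With 1 array per group the shared array could not be divided.

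The scrambled clone measured how far a stable clone departs without the knockdown, and 41 genes stood at least 2-fold higher and 46 at least 2-fold lower in SCR4 than in both other arrays. LHX9, a LIM homeobox factor, was 14.6-fold above the nearer array, at 10.15 in SCR4, 6.28 in WT and 6.04 in SI17. The myeloid surface gene IGSF6 was 6.75-fold higher, MPEG1, the macrophage perforin, 4.03-fold, the receptor CD244 3.82-fold, the secreted glycoprotein FSTL1 3.56-fold and the scaffold gene TANC1 3.44-fold. Of the higher genes named here, all but TANC1 were under the expression filter value in both WT and SI17, where they may be at background. DEFA4, a defensin of neutrophil granules, was 12.1-fold below the nearer array, and MSRB3, a methionine sulfoxide reductase, was 9.55-fold lower. DDAH1, which degrades asymmetric dimethylarginine, was 6.0-fold lower, SH3BGRL2 5.48-fold, MOXD1 5.16-fold and SLC35F1 4.40-fold. All of these lower genes but SLC35F1 were under the filter value in SCR4 and may be at background there. Against WT alone, SCR4 had 46 genes at least 2-fold higher and 66 at least 2-fold lower. The balance of higher and lower genes depended on the settings. At 1.5-fold it was 180 higher and 141 lower for genes apart in SCR4 and 209 and 182 against WT, under the 75th percentile filter 20 and 14, and 24 and 21, and at 3-fold 8 and 19, and 10 and 25.

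Neutrophil granule and progenitor genes had a median of -0.58 for SCR4 minus WT over 14 genes, 12 of them lower, and no random list had a lower median. The proteins they encode fill primary granules or mark early myeloid cells, and DEFA4 differed by -3.60, CTSG by -1.85 and MPO by -1.44, whereas the progenitor receptor FLT3 differed by 1.02. Monocyte and macrophage markers had a median of 0.17 over 20 genes, with CD36 at 1.76, CD86 at 1.38 and ITGAL at 1.30, whereas the neutrophil and monocyte alarmin S100A12 was at -1.23. Interferon-stimulated genes had a median of 0.22, with 16 of 22 higher, including TRIM22 at 0.84, IFI16 at 0.82 and OAS1 at 0.77, while LGALS3BP was at -1.24. Replication-dependent histone genes had a median of 0.21, with 29 of 32 higher. H2AC13 was at 0.56, H4C5 at 0.55, H4C4 at 0.40 and H4C2 at 0.54. Of these 32 genes, 30 lie on chromosome 6, and 22 lie in a run of 59 neighbouring genes there that was shifted upwards in SCR4, with a median of 0.21 for the histone genes and 0.14 for the 37 others. The 10 histone genes outside shifted runs had a median of 0.17, and the 2 on other chromosomes -0.01, so the histone result was not separable from the position of the genes, which was examined after seeing the data. Cholesterol biosynthesis genes had a median of -0.30, with 14 of 17 lower, among them DHCR7 at -0.91, SC5D at -0.49, TM7SF2 at -0.39 and STARD4 at -0.39. In all, 13 of the 33 lists lay above and 4 below the tails of random lists for SCR4 minus WT.

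Both clones had passed through transfection, drug selection and cloning, and 7 genes stood at least 2-fold apart from WT in both clones. Both differences use the same WT array, so a departure of that array alone would also give such genes. POPDC3, a membrane protein of striated muscle, was 2.27-fold above WT in the nearer clone, and ADRB1, the beta-1 adrenergic receptor, 2.07-fold. The cyclophilin PPIC was 2.52-fold below WT in the nearer clone, the integrin ITGA9 2.49-fold, the polarity scaffold MPP7 2.40-fold, the carboxypeptidase subunit CPN2 2.25-fold and CA2 2.05-fold. This count was 16 under the 25th percentile filter and 18 without a filter, so the genes that both clones shared depended on how dim a gene was allowed to be.

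Because clones of a leukaemia line can differ in chromosome content, differences were also summarised by chromosome. Genes of chromosome 12 had a median of -0.11 and a mean of -0.17 for SI17 minus WT over 524 genes, and genes of chromosome 20 had a median of 0.07 and a mean of 0.09 over 276 genes. For SCR4 minus WT, chromosome 5 had a median of -0.18 over 417 genes, chromosome 14 a median of -0.09 over 287, chromosome 8 a median of 0.16 over 324, chromosome 22 a median of 0.11 over 234, chromosome 2 a median of 0.10 over 602 and chromosome 17 a median of 0.09 over 608. Chromosome 12 held 8 of the 33 genes lowest in SI17, including ALX1, CD4, NAV3 and PTPRO, where its share of genes would give 1.83. Of 23 chromosomes, 8 lay outside the tails of random sets for SI17 minus WT, 8 for SCR4 minus WT and 16 for SI17 minus SCR4. These counts carry little weight, since exactly equal values held most random medians at 0, and by means, an alternative chosen after seeing the data, the counts were 14, 14 and 16.

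**Figure D3:**
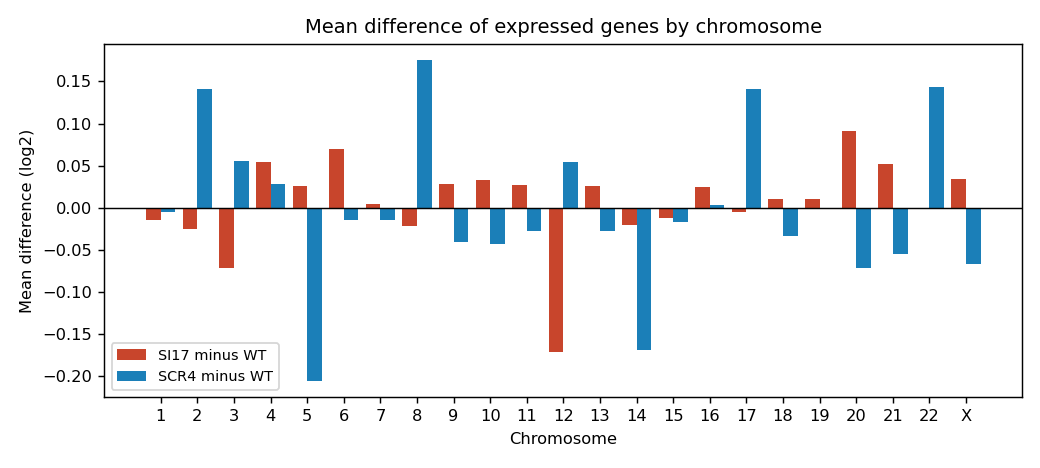
Mean log2 difference of the expressed genes of each chromosome for SI17 minus WT and SCR4 minus WT, as bars from 0. Chromosome 12 has a mean of -0.17 for SI17 minus WT, and chromosome 5 a mean of -0.21 for SCR4 minus WT.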

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

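The genes below met a rule fixed for all genes, and all tests of explanations in this part were chosen after the results had been seen. In 7 genes, SI17 and SCR4 departed from WT by at least 2-fold in opposite directions, which was not tested because each group had 1 array. As many genes, 7, departed by at least 2-fold in the same direction. FGL2, a secreted fibrinogen-like protein of macrophages and T cells, had an SI17 minus SCR4 difference of -2.71. F13A1, the coagulation factor subunit made by monocytes, had -2.69, PLBD1 -2.65, VAT1L -2.34 and CD180, a Toll-like receptor homologue of B cells and myeloid cells, -2.12. C3AR1 had 2.70 and POGLUT2 2.95. FGL2 and F13A1 were under the expression filter value in WT, at 7.01 and 7.45, and in SI17, at 6.01 and 6.24. POGLUT2 was under it in WT, at 6.70, and in SCR4, at 5.17. The departures of these genes between those arrays may therefore lie at background. PLBD1 was under it in SI17 alone, at 6.62, and VAT1L, CD180 and C3AR1 were over it on every array.

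WT lay between the clones in 64.7% of 5616 genes with no equal values. For that share, 12 settings of independent arrays summarised by median polish were simulated. Settings in which the clones varied more than WT gave 44.2% to 60.2%. Those in which all arrays varied alike gave 31.3% to 34.4%. These settings exclude nothing. Among 262 genes whose highest and lowest arrays differed by at least 1, WT lay between the clones in 75.95%. Requiring a wide range by itself favours genes whose clones moved apart, so an even split is not the right comparison. With the sign of SCR4 minus WT flipped at random the share averaged 68.1% (62.8 to 73.5), and with SCR4 minus WT shuffled among genes of like expression 62.5% (54.6 to 70.0). The observed share lay above both ranges by a small margin, but genes move in groups and each clone was a single array, so independent departures of the clones may still account for it. Outside the shifted chromosome runs the share was 72.77% of 191 genes, inside the flipped range and above the shuffled one, so a part played by the runs stays open, as does a placing of the clones at opposite ends of monocyte maturation, for which the granule and progenitor list of SI17 minus WT stood at percentile 85.21, between the bounds set for and against it, while the monocyte and macrophage list stood at percentile 0, within the bound set for it.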

How the results depend on the processing

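Of the values that answer a comparison, 116 alternatives stayed within the limits set for the same result and 37 moved. TYROBP moved in none of them. The 75th percentile filter tests fewer genes and gave 20 genes apart in SI17, 34 in SCR4 and 4 in both clones against WT, with 102 for SI17 against SCR4, 27 for SI17 against WT, 45 for SCR4 against WT and 16 chromosomes outside the tails for SCR4 minus WT. It also left 1 gene of the B cell list, XBP1, at 0.39 for SI17 minus SCR4, against a median of -0.34 over 5 genes. The 25th percentile filter gave 16 genes in both clones against WT and, for SI17 minus SCR4 and SI17 minus WT, 6 and 3 chromosomes. It also turned the osteoclast list median for SI17 minus SCR4 to 0.00248, over 16 genes in place of 10. Without a filter there were 18 genes in both clones against WT, 11 lists for SI17 minus SCR4, 6 higher and 5 lower lists for SI17 minus WT (4 and 9 with the filter), a correlation of 0.646 between the SI17 comparisons, and 1, 0 and 1 chromosomes for SI17 minus SCR4, SI17 minus WT and SCR4 minus WT. By construction a 1.5-fold threshold gave more genes, 142 apart in SI17, 321 in SCR4, 28 in both clones, 780 for SI17 against SCR4, 201 for SI17 against WT and 391 for SCR4 against WT, and a 3-fold threshold fewer, 8, 27, 0, 74, 11 and 35. The balance of higher and lower genes in SCR4 turned, from 41 and 46 apart and 46 and 66 against WT, to 180 and 141, and 209 and 182, at 1.5-fold and to 20 and 14, and 24 and 21, under the 75th percentile filter. Chromosomes outside the tails for SI17 minus WT and SCR4 minus WT were 14 (9 higher, 5 lower) and 20 (7 higher, 13 lower) with cyclic loess, against 8 (6 higher, 2 lower) and 8 (5 higher, 3 lower) as deposited. Quantile normalization gave 15 and 20 (7 higher, 13 lower). Alternatives chosen after seeing the data gave 24 genes apart in SI17 without genes in shifted runs, 16 and 20 chromosomes without genes of equal values, and 14 and 14 by chromosome means. For SCR4 minus WT the lower chromosomes outnumbered the higher in each alternative with 14 or more, against 5 and 3 as deposited. Of the other values, 921 list medians stayed and 397 moved (16 of the moved ones from fewer than 5 genes), as did 312 named gene values and 1 (HLA-DPA1). No paired analysis was possible because each group had 1 array, and leaving out a replicate was not possible for the same reason.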

Other observations

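Inflammatory cytokines and chemokines had a median of -0.31 for SI17 minus SCR4 over 14 genes, 0 for SI17 minus WT and 0.16 for SCR4 minus WT. The death ligand TNFSF10 differed by 0.93 between SCR4 and WT, the interleukin-1 receptor antagonist gene IL1RN by 0.73 and the monocyte attractant CCL2 by 0.73. Among pattern recognition genes the inflammasome sensor NLRC4 differed by 1.24 between SCR4 and WT and by -0.63 between SI17 and WT. NLRC4 was under the expression filter value in WT and SI17, at 7.16 and 6.53, so the latter difference may lie at background. Oxidative stress and metallothionein genes had a median of 0.08 for SI17 minus WT over 16 genes, 0.05 for SCR4 minus WT and 0.08 for SI17 minus SCR4, and only the first lay outside the tails of random lists. The metal-binding genes MT1X and MT1G differed from WT by 0.56 and 0.42 in SI17 and by 0.21 and 0.32 in SCR4, so both stood above WT in each clone. SLC7A11, the cystine transporter, differed by -1.82 between SCR4 and WT and by 0.20 between SI17 and WT. Cell cycle genes had a median of 0.05 for SI17 minus WT over 43 genes, 29 of them higher, with CCNB1 at 0.39.

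All tests in the rest of this part, and the settings behind them, were chosen after the results had been seen. In gene order on GRCh38.p14, means over 31 neighbouring genes, with differences limited to 1 either way and runs under 10 genes left out, passed the level of 1000 shuffles in 21 runs, 10 for SI17 minus WT with 488 genes and 11 for SCR4 minus WT with 903 genes. In SI17 the runs included NAP1L1 to PUS1 on chromosome 12 (187 genes, mean -0.23), RHNO1 to SOX5 on chromosome 12 (83 genes, -0.19) and KIF14 to CENPF on chromosome 1 (63 genes, -0.26). In SCR4 they included GPBP1 to CREBRF on chromosome 5 (279 genes, -0.25), PSMC1 to SIVA1 on chromosome 14 (58 genes, -0.37) and AZIN1 to ZFTRAF1 on chromosome 8 (84 genes, 0.31). With runs found again without genes differing from WT by 2-fold or more, so that the counted genes do not make the runs, 5 of the 33 genes lowest in SI17 lay in lower runs, where their share of genes would give 1.47. Of the 7 genes highest in SI17, 1 lay in a higher run, against 0.134. The scrambled clone showed an excess too. In SCR4, 8 of its 41 higher genes lay in higher runs, against 2.07, and 5 of its 46 lower genes in lower runs, against 2.04.

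An array shift that depends on expression level is argued against, since genes of like expression outside the runs moved by at most 0.0158 and the smallest run mean was 0.12 in size. A few strongly changed genes are argued against for the 17 of 21 runs found again without genes differing by 1.5-fold or more, a share just above the bound of 80% used here, and stay open for the other runs. Copy number differences between the cells may account for the runs, since in 5 of 6 runs found from every second gene the left-out genes shifted the same way by over 2 standard errors, but co-regulated neighbours would give the same result and DNA was not analysed here.

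Exactly equal values were common, in all 3 arrays for 16.1% of genes and in at least 2 arrays for 40.7%. Rounding is argued against, since 82 pairs of values differed by more than 0 and at most 0.001, while 6909 pairs were exactly equal. Median polish, the summary step of RMA, is a candidate explanation, since 96.95% of simulated unchanged probe sets summarised over 3 arrays had at least 2 equal values, though a simulation of unchanged probe sets cannot set the share in real ones. Medians of 0 in lists and chromosomes therefore reflect ties as well as small differences. For the equal values, no biological explanation was tested.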
